A study of Synechocystis sp. PCC 6803 with 12 samples.

How the data were processed

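Total RNA of the cyanobacterium Synechocystis sp. PCC6803 was measured on 12 single-colour Agilent arrays, 2 for each of 6 groups: wild type (WT) and the ΔcyaI mutant, each at 0, 3 and 24 h. The mutant lacks a soluble adenylate cyclase, an enzyme that makes the second messenger cyclic AMP. Per the labels' protocols, cultures grew at 30 °C under 130 µmol photons per square metre and second, and were bubbled with air holding 5% CO2 or with ambient air holding 0.04%. RNA was extracted with hot phenol and labelled directly with Cy3 in portions of 2 µg, without cDNA, per the labels' protocols, so that a probe reads the RNA strand complementary to it. Group and replicate were taken from the sample titles. The series text calls the samples of a group biological replicates and states that the WT raw data also served in an experiment with another mutant. The labels conflict on the carbon supply: the treatment entry calls 0 h low carbon and the later times high carbon, whereas the treatment protocol has cells moved to low carbon before 3 and 24 h. Groups are therefore named by genotype and hours, and no direction of the CO2 change is assumed.

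Spot intensity was extracted with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited processed intensity is background-subtracted and spatially detrended within each array, per the file headers, with spots near background given a small positive surrogate value; the median spot intensity and local background are raw scanner values. The deposited flags on whether a spot was well above background, saturated or an outlier are other columns of the same files and hold 0 or 1. The authors' table of log2 values names limma as its tool, per the submitters' processing notes, and the series text says that WT and mutant arrays were normalized together; its normalization method is not given in the sources used here. Within each array those log2 values from the authors followed the rank order of the median spot intensity (Spearman correlation of 1), with no background subtracted. Their array medians ran from 9.75 to 10.25, so their centring stays unknown, and they served as an alternative.

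Each array held 62334 spots, of which 1319 were control spots and 61015 were probes with 1 spot each. The 31 probes with an outlier flag on any array were left out, which left 60984, and no probe was saturated. The log2 of the processed intensity minus the array's 75th percentile was the value analysed. The 37703 probes well above background on both arrays of at least 1 group were tested. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) fitted 6 group means over all 12 arrays, with 6 residual and 3.35 prior degrees of freedom. Calls were made at an adjusted p under 0.05 (Benjamini-Hochberg over the probes tested, 2-sided), and all adjusted p-values for probes come from this fit. Errors of changes are standard errors (SE) of that fit and errors of levels are standard deviations (SD). The number of arrays limits the precision. A probe not well above background on either array of a group has only a bound there. For these, the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest well-above-background level and the probe's own value, and is given as "at least N-fold". The lowest well-above-background level lay between -2.60 and -1.02 on the normalized log2 scale, and was highest in the ΔcyaI arrays at 24 h. An adjusted p printed with a bound belongs to the fitted change, not to the bound. That fit uses the dim group's values under detection, some of them surrogate values. Surrogate values of replicate arrays may differ only by the arrays' lowest values, so such a p need not measure the spread between cultures. Probes not well above background in either group compared have no bound but stay in the counts of calls. Such calls ranged from 395 in ΔcyaI 3 h vs 0 h to 1862 in ΔcyaI 24 h vs 0 h. Calls on probes dim in only 1 group did not all have a bound in the direction of the call. In ΔcyaI 24 h vs 0 h 4757 of 7713 had one, in ΔcyaI vs WT at 24 h 2556 of 4471, and in ΔcyaI 3 h vs 0 h 5858 of 6123.

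The files do not pair probes with genes: 60866 probes carry only a running number, and 149 are named after a CRISPR array (49 for CRISPR1, 55 for CRISPR2, 38 for CRISPR3) or a leader (4 for LEADER1, 3 for LEADER2). Mean signals of consecutive running numbers were uncorrelated (-0.00129), so a number holds no position. All 26 gene lists fixed before the data were examined (297 members, covering carbon uptake, photosynthesis, nitrogen, stress and other functions, and cyaI with its neighbours) matched 0 probes, so no list result exists and the deletion could not be checked in these arrays. Named probes follow the limits of a rule fixed at the same time: for a comparison of 2 groups, the 8 largest changes each way among named features called, with both arrays of 1 group beyond both of the other, and 5 each way for a difference of changes. That rule covered features with a gene locus ID or the name of a regulatory RNA, which no probe carries. It was applied to CRISPR and leader probes only after the probe names were read. For a difference of changes the text names and ranks only probes well above background on at least 1 array of each of the 4 groups, a limit set after the values were seen. Running-number probes are limited to 2 each way, and 1 CRISPR probe is not reported here, by name or in the plot of levels, though it stays in the counts and medians of its group. The 5 probe groups come from the probe names and were set up before their values were examined, though not among the lists fixed beforehand. Stretches of probe numbers within a CRISPR array were chosen after the values were seen. Whether the number in a CRISPR probe's name is its place in the array is not given in the sources used here. Probe groups were tested with camera at a preset correlation of 0.01, adjusted over 45 tests, and with an estimated correlation and with fry as alternatives.

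The arrays lie on 3 slides of 4, with WT 0 h and WT 24 h on slide 1, ΔcyaI 0 h and ΔcyaI 24 h on slide 2, and both genotypes at 3 h on slide 3, which was scanned on another day. Only WT 24 h vs 0 h, ΔcyaI 24 h vs 0 h and ΔcyaI vs WT at 3 h lie within a slide, and their fit to the 4 arrays of the slide equals the fit to the arrays of the groups compared. In the other comparisons of 2 groups slide and group cannot be told apart, and the same holds for the difference of the 3 h changes, whereas a constant offset between slides cancels in the difference of the 24 h changes. Slide as a block could not be fitted since each group lies on 1 slide.

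The steps were tested on simulated data of 37703 probes with 200 changed probes per size. For WT 3 h vs 0 h, 95% of changes of 2 on the log2 scale, 53.5% of changes of 1 and 3.5% of changes of 0.5 were called, and 2.25% of the calls were false. For the difference of the 24 h changes the shares were 80%, 15% and 0%, with 7.32% false calls. All other probes were simulated without a change in the comparison, with noise drawn from the fitted spreads and no offset between slides or scalings. In the data 43.3% of the probes were called for WT 3 h vs 0 h. The adjusted p depends on the share of changed probes, so the simulated shares need not hold for the data. Alternatives covered background correction with normexp (offset 50) and quantile normalization, quantile normalization alone, centring on the median, the authors' values, the filter on dim probes, eBayes with trend and robust, replicate blocks, only the arrays compared, a fold threshold and leaving out each array. The planned normexp correction on the mean spot signal was run on the median signal, since the mean is not a column used here. That change, a common floor at the highest detection level and counts among probes measured in both groups, or in all 4 for a difference of changes, were chosen after seeing the data. Taking the median of probes per feature would change nothing with 1 probe per feature. Correlations across probes were counted as moved when they shifted by more than their SD over the fits without 1 array. Figures were drawn with matplotlib in Python.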

Results

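The arrays measured RNA of WT and ΔcyaI cells at 0, 3 and 24 h, with 2 arrays per group. Between 38% and 55.2% of the 60984 probes were well above background on an array, the lowest shares being those of ΔcyaI at 24 h (38% and 41.3%). Replicate arrays correlated at 0.973 (WT 0 h) to 0.992 (ΔcyaI 3 h) across the 37703 probes tested. Since the files do not pair probes with genes, the named features are probes for the 3 CRISPR arrays, which are transcribed and cut into the guide RNAs of bacterial immunity against foreign DNA, and for 2 leaders, the stretches next to such arrays. Other probes are given as counts and by running number. The labels contradict each other on whether carbon supply rose or fell after 0 h, so changes are given by hours.

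In WT at 3 h against 0 h, which asks how the transcriptome changed after the shift, 12 of 30 CRISPR2 probes were lower and 2 higher. Their median log2 change was -0.27 (-1.26 for the 18 measured in both groups and -0.46 with dim probes at their bound), but 0.34 with the authors' processed values, where the median of all probes was 0.40. R_CRISPR2-4 changed by -2.61 (SE 0.37, adjusted p = 0.000406), R_CRISPR2-12 by -2.23 (SE 0.21, adjusted p = 2.36e-05) and R_CRISPR2-8 by -1.92 (SE 0.12, adjusted p = 2.21e-06). The level of R_CRISPR2-8 was 1.74 ± 0.01 at 0 h and -0.18 ± 0.04 at 3 h (SD, n = 2, log2 over the 75th percentile). The group's adjusted p with camera was 0.0359, and 0.689 with an estimated correlation, 0.0523 with quantile normalization, 0.0564 with no filter on dim probes, 0.0713 without WT 0 h replicate 2 and 0.0667 without WT 3 h replicate 1. Both LEADER2 probes tested were lower, with a median of -1.31 (camera adjusted p = 0.122, 0.499 with an estimated correlation, 0.00756 with the authors' processed values and 0.00226 with fry, which does not compare a group with other probes), and none of the 4 LEADER1 probes was called. Of CRISPR3, 5 of 35 probes were higher, R_CRISPR3-3 by 0.66 (SE 0.13, adjusted p = 0.00297), with a group camera adjusted p of 0.274 that was 0.0133 with normexp and 0.0491 without WT 0 h replicate 2, and of CRISPR1, 6 of 43 were lower, with a median of -0.15 (camera adjusted p = 0.564) that was 0.16 among the 21 measured in both groups and 0.34 with the authors' processed values. Across all probes, 7529 were higher and 8797 lower, and among those measured in both groups 5348 were higher and 6430 lower. The largest rises were those of SYN-CR-76-28561 (10.71, SE 0.26, adjusted p = 1.87e-08), well above background on 1 of 2 arrays at 0 h, and SYN-CR-76-53562 (9.96, SE 0.19, adjusted p = 1.87e-08). SYN-CR-76-23940 was at least 33.2-fold lower and SYN-CR-76-34089 at least 29.5-fold lower at 3 h, both not well above background there. The 2 groups lie on different slides, so slide and time cannot be told apart, and the authors' processed values gave 22530 higher and 1795 lower. The median of all probes shifted by 0.44 with those values.

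In WT at 24 h against 0 h, within 1 slide, 13 of 43 CRISPR1 probes were higher and 1 lower. Their median was 0.75 among the 18 measured in both groups but -0.03 over all 43, where it was 0.15 with the authors' processed values, which put the median of all probes at 0.21 (camera adjusted p = 0.252). Among probes above background on all 12 arrays the median was 0.75 and the camera adjusted p 0.000896, and that p was 0.0218 with a common floor and 0.0406 without WT 24 h replicate 2. R_CRISPR1-49 rose by 1.26 (SE 0.21, adjusted p = 0.00115) and R_CRISPR1-12 by 1.19 (SE 0.19, adjusted p = 0.000892). CRISPR3 had 9 of 35 probes higher and none lower (median 0.23, camera adjusted p = 0.0265, and 0.776 with an estimated correlation). Without WT 0 h replicate 1 that p was 0.23, without WT 24 h replicate 1 0.165, with the authors' processed values 0.0642, with a common floor 0.0536 and with fry 0.117. LEADER1 fell in 3 of 4 probes (median -0.84, camera adjusted p = 0.0245, 0.499 with an estimated correlation and 0.0585 with quantile normalization), and R_LEADER2-3 changed by -1.17 (SE 0.20, adjusted p = 0.00151). The LEADER2 camera adjusted p was 0.161, 0.499 with an estimated correlation, 0.0471 with the authors' processed values and 0.00743 with fry. CRISPR2 changed in 3 of 30 probes. Across all probes, 6644 were higher and 7274 lower. SYN-CR-76-28561 rose by 10.56 (SE 0.26, adjusted p = 1.36e-08) and SYN-CR-76-53562 by 10.07 (SE 0.19, adjusted p = 1.11e-08), while SYN-CR-76-23940 was at least 26.3-fold and SYN-CR-76-3038 at least 24.2-fold lower. The authors' processed values gave 7606 higher and 2133 lower probes.

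In ΔcyaI at 3 h against 0 h, CRISPR1 and CRISPR3 probes were higher and both LEADER2 probes were lower. CRISPR1 had 27 of 43 probes higher and none lower (median 0.65, camera adjusted p = 0.00158, and 0.565 with an estimated correlation). CRISPR3 had 23 of 35 higher and none lower (median 0.68, camera adjusted p = 0.00622, and 0.689 with an estimated correlation). Examples were R_CRISPR1-26 (1.09, SE 0.21, adjusted p = 0.00147) and R_CRISPR3-22 (1.09, SE 0.34, adjusted p = 0.0185). CRISPR2 went both ways, with 11 probes higher and 8 lower and a median (0.45) and mean (-0.03) of opposite sign. Among probes above background on all 12 arrays its median was -0.68 (camera adjusted p = 0.0637), where the median of all probes was 0.17. R_CRISPR2-4 changed by -2.04 (SE 0.37, adjusted p = 0.000984). R_LEADER2-2 changed by -2.85 (SE 0.28, adjusted p = 1.81e-05), from 4.06 ± 0.27 to 1.20 ± 0.06 (SD, n = 2), and R_LEADER2-3 by -2.70 (SE 0.20, adjusted p = 3.02e-06). The LEADER2 camera adjusted p was 0.0549, and 0.499 with an estimated correlation. It was 0.0234 with normexp, 3.11e-08 with the authors' processed values, 0.0355 among probes above background on all 12 arrays and 8.01e-05 with fry. Without 1 array the LEADER2 median ranged from -2.96 to -2.60. In all, 13574 probes were higher and 11318 lower. SYN-CR-76-41456 was at least 124-fold higher and SYN-CR-76-54947 at least 63.1-fold higher, and SYN-CR-76-7973 and SYN-CR-76-38974 were at least 50.5-fold and 43.7-fold lower. Slide and time cannot be told apart here, and the split of calls followed the scaling: with arrays centred on their medians 9820 were higher and 13090 lower, and with the authors' processed values 4385 and 8976.

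In ΔcyaI at 24 h against 0 h, within 1 slide, CRISPR1 was higher in 32 of 43 probes and lower in none (median 1.02, camera adjusted p = 1.05e-05, and 0.499 with an estimated correlation). R_CRISPR1-38 rose by 1.89 (SE 0.26, adjusted p = 0.000175) and R_CRISPR1-26 by 1.61 (SE 0.21, adjusted p = 0.000117). CRISPR3 had 22 of 35 probes higher and 1 lower (median 0.74, camera adjusted p = 0.00326, 0.689 with an estimated correlation and 0.134 with no filter on dim probes), among them R_CRISPR3-17 (1.56, SE 0.19, adjusted p = 8.1e-05). R_LEADER2-2 changed by -3.15 (SE 0.28, adjusted p = 9.74e-06) and R_LEADER2-3 by -2.87 (SE 0.20, adjusted p = 2.14e-06), and R_CRISPR2-4 was at least 4.48-fold lower. The LEADER2 camera adjusted p was 0.0549, and 0.499 with an estimated correlation. It was 0.0232 with normexp, 0.0396 with arrays centred on their medians, 6.64e-09 with the authors' processed values, 0.0268 among probes above background on all 12 arrays and 5.98e-05 with fry. Without 1 array the LEADER2 median ranged from -3.21 to -2.81. CRISPR2 had 8 probes higher and 9 lower of 30, with a median of 0.16 that was -0.053 with the authors' processed values, where the median of all probes was -0.10, and -0.70 among probes above background on all 12 arrays (camera adjusted p = 0.813, and 0.0438 among the latter). Over all probes, 13806 were higher and 12299 lower. Among probes measured in both groups, 10377 were higher and 6153 lower. SYN-CR-76-41456 was at least 125-fold and SYN-CR-76-51500 at least 108-fold higher, the latter bound being 49.8 without ΔcyaI 24 h replicate 1 and 233 without ΔcyaI 24 h replicate 2, and SYN-CR-76-59557 and SYN-CR-76-6694 at least 37.9-fold and 37.7-fold lower. The ΔcyaI arrays at 24 h had the fewest probes above background, and the authors' processed values gave 3819 higher and 10773 lower. With no filter on dim probes 30712 were higher and 13174 lower.

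**Figure D1:**
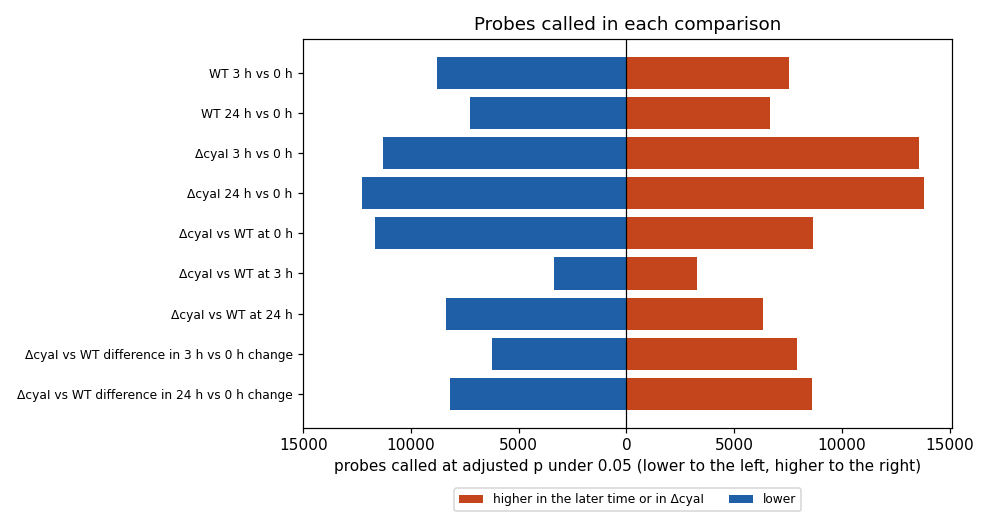
Number of probes called higher (right, red) and lower (left, blue) at a limma adjusted p under 0.05 in each of the 9 comparisons, of 37703 tested, with 2 arrays per group. ΔcyaI 24 h vs 0 h had 26105 calls and ΔcyaI vs WT at 3 h had 6666; with the authors' processed values the larger side, higher or lower, was the opposite one in all 9.

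Changes over time in the genotypes were compared across probes, which are not independent replicates. At 3 h the log2 changes of WT and ΔcyaI correlated at r = 0.686 (Spearman 0.624), and at 24 h at r = 0.609 (Spearman 0.512). Both genotypes at 3 h lie on slide 3, and their 0 h arrays lie on other slides. An offset of slide 3 would enter both 3 h changes alike and could raise their correlation and the number of shared calls. The 24 h changes each lie within a slide, so the values at 3 h and 24 h are not directly comparable. Of 12614 probes called in both genotypes at 3 h, 90.9% changed the same way, with 5476 higher in both and 5987 lower in both, against 2711 and 2641 for independent lists. At 24 h the share was 85.6% of 11010, with 4515 higher in both and 4912 lower in both, against 2433 and 2373. The SD of the changes was larger in ΔcyaI, 1.31 times that of WT at 3 h and 1.45 times at 24 h. Within a genotype the 3 h and 24 h changes share the 0 h arrays. They correlated at 0.807 in WT and 0.930 in ΔcyaI, against 0.492 and 0.501 for simulated unchanged groups, with covariances of 0.939 and 2.05 against 0.0288 and 0.0289. A split of the 2 arrays at 0 h, with 1 for each change, was not run, and part of the excess may come from the shared arrays.

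**Figure D2:**
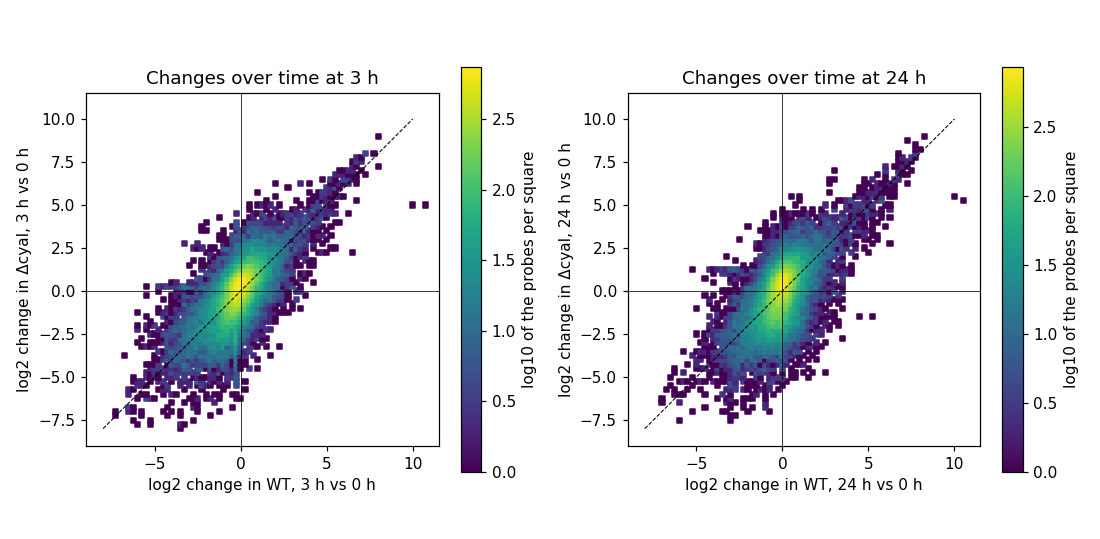
Log2 change in ΔcyaI (vertical axis) against that in WT (horizontal axis) at 3 h and at 24 h against 0 h, as squares of 0.25 log2 coloured by the log10 of the number of probes, with 2 arrays per group and the dashed line marking equal change. The squares spread to both sides of the line, with Pearson correlations of 0.686 and 0.609 across 37703 probes.

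Whether the change over time differed between genotypes was tested directly. In the 3 h difference a constant offset of slide 3 cancels, but one between slides 1 and 2, which hold the 0 h arrays, stays. Slide and difference can therefore not be told apart at 3 h, whereas a constant offset between slides cancels in the 24 h difference. Both LEADER2 probes had a lower change in ΔcyaI than in WT. For R_LEADER2-2 the difference was -1.84 (SE 0.40, adjusted p = 0.0068) at 3 h and -2.42 (SE 0.40, adjusted p = 0.00146) at 24 h, and for R_LEADER2-3 it was -1.09 (SE 0.28, adjusted p = 0.0156) and -1.70 (SE 0.28, adjusted p = 0.0016). As a group LEADER2 had a camera adjusted p of 0.0792 at 3 h and 0.0549 at 24 h, and of 0.499 at both times with an estimated correlation. The p was 0.0241 and 0.0143 with normexp, 8.47e-06 and 3.11e-08 with the authors' processed values, and 0.00743 and 0.00225 with fry. At 24 h it was also 0.0396 with arrays centred on their medians, 0.0268 among probes above background on all 12 arrays, and 0.0397 to 0.0469 without ΔcyaI 0 h replicate 1, ΔcyaI 24 h replicate 2 or either WT 0 h array. CRISPR1 had a higher change in ΔcyaI in 17 of 43 probes at 3 h, with a median difference of 0.91 (camera adjusted p = 0.000148) that was -0.14 with the authors' processed values, where the median of all probes was -0.45. At 24 h 16 probes had a higher change and 1 a lower one (median 0.92, camera adjusted p = 0.000423), and both p-values were 0.499 with an estimated correlation. Of these, 15 of the 17 at 3 h and 15 of the 16 at 24 h were not well above background in at least 1 of the 4 groups, so their change was not measured in both genotypes. Of the CRISPR1 probes measured in all 4 groups, 2 of 19 had a higher change at 3 h (median 0.48), and at 24 h 1 of 16 had a higher and 1 a lower change (median 0.27). Among probes above background on all 12 arrays the camera adjusted p was 0.0812 at 3 h and 0.871 at 24 h, and with no filter on dim probes it was 0.058 at 24 h. CRISPR2 differed upwards in 10 of 30 probes and downwards in 1 at 3 h, with a median of 0.58 that was -0.30 with the authors' processed values (camera adjusted p = 0.031, and 0.689 with an estimated correlation). That p was 0.0561 without ΔcyaI 0 h replicate 1, 0.0893 without WT 0 h replicate 2 and 0.0626 without WT 3 h replicate 1. CRISPR3 had a median difference of 0.57 at 3 h (camera adjusted p = 0.0792), which was 0.33 with normexp (adjusted p = 0.0135), 0.60 with a common floor (adjusted p = 0.000639) and -0.16 with the authors' processed values (adjusted p = 0.000124, upwards of other probes), and the p was 0.0157 to 0.0222 without WT 0 h replicate 1, WT 3 h replicate 2 or ΔcyaI 0 h replicate 2. At 24 h it was 0.32 (camera adjusted p = 0.27, and 0.0155 with a common floor). For CRISPR2 at 24 h, 1 probe had a higher and 6 a lower change (median 0.052, mean -0.13, camera adjusted p = 0.634). R_CRISPR2-12 differed by 1.55 (SE 0.29, adjusted p = 0.00356) at 3 h, and R_CRISPR2-6 by -1.57 (SE 0.17, adjusted p = 0.000149) at 24 h. At 3 h, 7905 probes differed upwards and 6229 downwards, and at 24 h 8595 and 8214. Among probes measured in all 4 groups 5544 differed upwards and 4035 downwards at 3 h, and 6313 and 3910 at 24 h. SYN-CR-76-53562 differed by -4.85 (SE 0.27, adjusted p = 1.07e-05) at 3 h and -4.58 (SE 0.27, adjusted p = 7.71e-06) at 24 h. SYN-CR-76-6195 differed by 4.18 (SE 0.24, adjusted p = 7.02e-06) at 24 h, and SYN-CR-76-57624, well above background on 1 of 2 ΔcyaI arrays at 0 h, by 4.19 (SE 0.70, adjusted p = 0.00195) at 3 h (3.22 without ΔcyaI 0 h replicate 2 and 5.16 without replicate 1). With the authors' processed values 361 probes differed upwards and 14700 downwards at 3 h, 502 and 10457 at 24 h; with arrays centred on their medians the 3 h split was 4467 and 7840. With no filter on dim probes 12880 differed upwards and 6489 downwards at 3 h, and 23661 and 8933 at 24 h. Without ΔcyaI 3 h replicate 1 the 3 h count was 9266.

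At 0 h, before the shift, CRISPR3 was higher in ΔcyaI in 33 of 35 probes and lower in none, with a median of 3.19 (2.67 among the 19 measured in both groups and 2.36 with dim probes at their bound, camera adjusted p = 3.72e-21, and 0.394 with an estimated correlation). R_CRISPR3-15 was at least 8.06-fold higher (adjusted p = 3.89e-07), at 1.28 ± 0.18 (SD, n = 2) in ΔcyaI and not well above background in WT, and R_CRISPR3-18 was higher by 4.68 (SE 0.51, adjusted p = 7.62e-05), or by 3.66 without WT 0 h replicate 1 and 5.70 without WT 0 h replicate 2. CRISPR1 went both ways, with 22 of 43 probes higher and 14 lower. R_CRISPR1-18 was at least 11.4-fold higher (adjusted p = 1.9e-07) and R_CRISPR1-49 at least 4.05-fold lower (adjusted p = 1.02e-06). The CRISPR1 median over all 43 probes was 1.69 (camera adjusted p = 0.00217, 0.566 with an estimated correlation, 0.0502 with the authors' processed values and 0.12 with a common floor), that of the 20 probes measured in both groups was -0.72, and it was 0.28 with dim probes at their bound. A filter on probes above background on all 12 arrays removes those dim in WT and leaves 13 of CRISPR1 probes 1 to 14 and 2 of probes 15 to 41. Their median was -0.81 (camera adjusted p = 0.00944). Of the 13 tested probes 1 to 14, 12 were called lower, whereas no tested probe of 15 to 41 had a fitted change below 0.055. Where a bound showed a rise (18 of the latter), the lowest was at least 1.14-fold. CRISPR2 had 18 of 30 probes higher and none lower (median 0.75, camera adjusted p = 0.000104, and 0.499 with an estimated correlation). The CRISPR2 median was 0.35 among the 18 probes measured in both groups and 0.33 with dim probes at their bound. Both LEADER2 probes were higher, by a median of 1.19 (camera adjusted p = 0.12, 0.499 with an estimated correlation, 0.000516 with the authors' processed values and 0.00492 with fry). Among all probes 8666 were higher and 11674 lower, and among those measured in both groups 6337 were higher and 9100 lower. Of the calls, 961 fell on probes not well above background in either group. SYN-CR-76-60112 was at least 16.8-fold and SYN-CR-76-60535 at least 14.6-fold higher, and SYN-CR-76-19992 and SYN-CR-76-48067 at least 13-fold and 22.2-fold lower. Genotype and slide cannot be told apart at 0 h, and with the authors' processed values 26071 probes were higher and 716 lower, the median of all probes lying 0.61 above its main value. With arrays centred on their medians 10277 were higher and 8132 lower, and with no filter on dim probes 9614 were higher and 27826 lower.

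At 3 h both genotypes lie on 1 slide, and all 35 CRISPR3 probes were higher in ΔcyaI. Their median was 3.77 (2.70 among the 21 measured in both groups and 2.82 with dim probes at their bound, camera adjusted p = 5.5e-44, and 0.323 with an estimated correlation). R_CRISPR3-15 was at least 18.1-fold higher (adjusted p = 7.73e-07) and R_CRISPR3-18 higher by 5.61 (SE 0.51, adjusted p = 0.000106), from -1.41 ± 0.08 in WT to 4.19 ± 0.05 in ΔcyaI (SD, n = 2). CRISPR1 had 26 of 43 probes higher and 5 lower. R_CRISPR1-18 was at least 25.7-fold higher (adjusted p = 1.79e-07), R_CRISPR1-25 at least 11.7-fold higher and R_CRISPR1-49 at least 3.41-fold lower (adjusted p = 2.95e-06), while R_CRISPR1-9 changed by -0.94 (SE 0.13, adjusted p = 0.0015). The CRISPR1 median was 2.68 over all 43 probes (camera adjusted p = 2.21e-11, and 0.493 with an estimated correlation) and -0.40 over the 19 measured in both groups, and it was 1.19 with dim probes at their bound. The CRISPR1 probes above background on all 12 arrays, mainly from numbers 1 to 14, had a median of -0.47 (camera adjusted p = 0.0308). Of the 13 tested probes 1 to 14, 3 were called lower and none higher, whereas the lowest fitted change among tested probes of 15 to 41 was 1.19. Of the latter, 22 were not well above background in WT and have only a bound, the lowest being at least 1.35-fold higher. CRISPR2 had 20 of 30 probes higher and none lower (median 0.91, 0.70 among the 21 measured in both groups and 0.83 with dim probes at their bound, camera adjusted p = 8.5e-16, and 0.323 with an estimated correlation), among them R_CRISPR2-15 at least 11.2-fold. Over all probes 3287 were higher and 3379 lower. SYN-CR-76-5311 was at least 24.7-fold and SYN-CR-76-32141 at least 23.4-fold higher, and SYN-CR-76-6541 and SYN-CR-76-26425 at least 5.83-fold and 4.13-fold lower. The count of 6666 fell to 2679 without ΔcyaI 3 h replicate 1, to 2835 without ΔcyaI 3 h replicate 2 and to 3481 without WT 3 h replicate 1, and the authors' processed values called 2567.

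**Figure D3:**
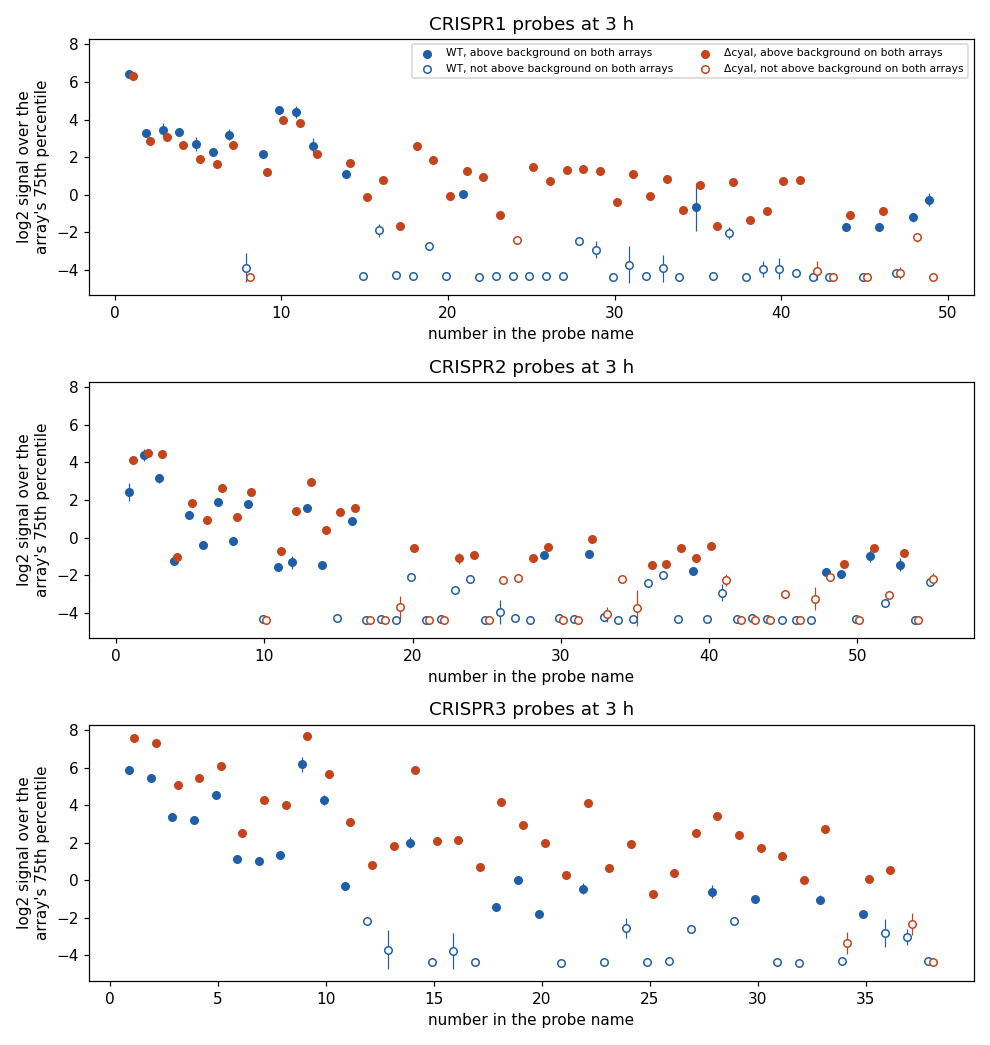
Mean level at 3 h (vertical axis, log2 of the signal over the array's 75th percentile, bars of 1 SD, n = 2) of the CRISPR probes reported, by the number in the name (horizontal axis), for WT in blue and ΔcyaI in red, with open circles for probes not well above background on both arrays. In CRISPR3 all 35 tested probes are higher in ΔcyaI, and in CRISPR1 the median difference was -0.53 for probes 1 to 14, whereas 22 of probes 15 to 41 were above background on both ΔcyaI arrays and neither WT array.

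At 24 h CRISPR3 was again higher in ΔcyaI in 35 of 35 probes, with a median of 3.59 (2.64 among the 22 measured in both groups and 2.68 with dim probes at their bound, camera adjusted p = 3.94e-30, and 0.323 with an estimated correlation). R_CRISPR3-16 was at least 19.9-fold higher (adjusted p = 5.91e-06). CRISPR1 had 26 of 43 probes higher and 11 lower, R_CRISPR1-18 at least 32.0-fold higher (adjusted p = 1.04e-07) and R_CRISPR1-49 at least 3.57-fold lower (adjusted p = 3.03e-06). The CRISPR1 median was 2.88 over all probes (camera adjusted p = 1.95e-07, and 0.499 with an estimated correlation) and -0.63 over the 16 measured in both groups, and it was 1.17 with dim probes at their bound. Those CRISPR1 probes above background on all 12 arrays had a median of -0.73 (camera adjusted p = 0.000875). Of the 13 tested probes 1 to 14, 9 were called lower and none higher, whereas the lowest fitted change among tested probes of 15 to 41 was 0.73. Of the latter, 23 were not well above background in WT and have only a bound, the lowest being at least 1.47-fold higher. CRISPR2 had 15 probes higher and 4 lower (median 0.56, 0.39 among the 18 measured in both groups, camera adjusted p = 0.00115), with R_CRISPR2-4 at least 3.06-fold lower. That p was 0.499 with an estimated correlation, 0.0721 with the authors' processed values, 0.246 with a common floor and 0.934 among probes above background on all 12 arrays. LEADER1 was higher in 3 of 4 probes (median 0.53, camera adjusted p = 0.0339) and LEADER2 lower in both (median -0.87, camera adjusted p = 0.184, 0.499 with an estimated correlation, 0.00401 with the authors' processed values and 0.0117 with fry). The LEADER1 p was 0.499 with an estimated correlation, 0.057 without WT 24 h replicate 2 and between 0.0541 and 0.125 with normexp, quantile normalization, centring on the median, no filter, and probes above background on all 12 arrays. Over all probes 6340 were higher and 8390 lower, but among those measured in both groups 4850 were higher and 3730 lower. SYN-CR-76-7515 was at least 18.3-fold and SYN-CR-76-48510 at least 20.2-fold higher, and SYN-CR-76-19925 and SYN-CR-76-24739 at least 4.57-fold and 8.23-fold lower. Genotype and slide cannot be told apart at 24 h, and 11913 probes were higher and 4801 lower with arrays centred on their medians, 3552 and 1507 with the authors' processed values, and 19316 and 10057 with no filter on dim probes. The count of 14730 fell to 8913 without WT 24 h replicate 2, to 9200 without ΔcyaI 24 h replicate 2, to 9448 with a common floor and to 8580 among probes measured in both groups.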

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

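The tests of explanations in this part were chosen only after the results were seen, while the tests of differences between genotypes in the change over time were planned. The change over time differed between genotypes in 14134 probes at 3 h (9266 without ΔcyaI 3 h replicate 1) and 16809 at 24 h (10223 of them among probes measured in all 4 groups). At 3 h, slide and difference cannot be told apart, since the 3 h arrays lie on 1 slide and the 0 h arrays of the genotypes on 2 others. Among probe groups, the difference was a median of 0.91 for CRISPR1 and 0.58 for CRISPR2 at 3 h (camera adjusted p = 0.000148 and 0.031, and 0.499 and 0.689 with an estimated correlation), and 0.92 for CRISPR1 at 24 h (adjusted p = 0.000423, and 0.499 with an estimated correlation). The 3 h values were -0.14 and -0.30 with the authors' processed values, where the median of all probes was -0.45. For CRISPR1 probes above background on all 12 arrays the median difference was 0.46 at 3 h (adjusted p = 0.0812) and 0.26 at 24 h (adjusted p = 0.871). Among called running-number probes well above background on at least 1 array of each of the 4 groups, the largest differences at 3 h were 4.19 for SYN-CR-76-57624, 3.89 for SYN-CR-76-36411, -5.73 for SYN-CR-76-28561 and -4.85 for SYN-CR-76-53562. At 24 h they were 4.27 for SYN-CR-76-59988, 4.18 for SYN-CR-76-6195, -5.33 for SYN-CR-76-28561 and -4.58 for SYN-CR-76-53562. In 1 of the 4 groups SYN-CR-76-57624, SYN-CR-76-36411, SYN-CR-76-28561 and SYN-CR-76-59988 were above background on 1 of 2 arrays. Without ΔcyaI 0 h replicate 2 and replicate 1 the 3 h differences were 3.22 and 5.16 for SYN-CR-76-57624, and 2.95 and 4.83 for SYN-CR-76-36411. Control spots not used in the comparisons also gave signal, above the highest share of 0.325% among negative controls. A median of 49% of E1A spots, 14% of ERCC spots, 19.2% of ETG spots and 100% of bright corner spots, which serve to place the grid, were well above background.

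CRISPR1 probes 15 to 41, numbered as in their names, which need not give their place in the array, were seen in ΔcyaI and mostly not in WT. At 3 h, where both genotypes share a slide, 22 of the 27 were above background on both ΔcyaI arrays and on neither WT array, which argues against the slide. An array-wide shift moves all probes of an array alike and cancels once the median of all probes is subtracted. A comparison with that median can therefore not test scaling. The block, chosen after its values were seen, lay above that median at 3 h by 0.96 with the unscaled median signal, the lowest of the settings. With a common floor it lay above by 1.69, so its difference did not come only from values under that floor. The median of probes 1 to 14 was -0.53 at 3 h, and of the 13 tested none was called higher and 3 were called lower. These probes did not share the rise of probes 15 to 41. The boundary was drawn after the values were seen, so their median is no test of a rise of the whole CRISPR1 transcript. The pattern was not limited to this block. Of CRISPR3 probes 11 to 33, also chosen after the values were seen, 12 of 23 were above background on no WT array and 22 on all 6 ΔcyaI arrays. CRISPR1 probes 48 and 49 went the other way, seen on all 6 WT arrays and on no ΔcyaI array. A difference in spacer content between the 2 strains and an effect of cyaI both stay open: that probes dim on every WT array lie together by number (18 switches among 49 probes, permutation p = 0.046, 1-sided, 100000 resamples) restates the observation that prompted the test and bears on the array only if the number is the place in it, and no DNA was measured.

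More probes differed between genotypes at 0 h than at 3 h. The ratio of the 0 h to the 3 h count was at least 2.29 over the scalings, floors and filters run. It was 10.4 with the authors' processed values, so its size changed with the scaling. Although the 3 h count fell when an array was left out, the lowest 0 h count without 1 array was 3.16 times the highest 3 h count without 1 array. The larger 0 h count thus held in every setting run and without any single array. A contribution of scaling to its size is not excluded by these settings. Only 1 slide holds both genotypes, so whether the smaller 3 h count comes from sharing a slide cannot be told apart from time. A constant offset between the WT and ΔcyaI slides stays open too: the differences at 0 h correlated across probes at 0.266 with those at 24 h, on the same 2 slides, and at 0.306 with those at 3 h, but differences particular to 24 h could hide such an offset. A genotype difference that depends on time stays among the open explanations.

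Some probes were above background on all 6 arrays of 1 genotype and on none of the other, 50 in WT and 96 in ΔcyaI. Replicate arrays are alike, so only the 10 divisions of the 6 groups into 3 and 3 bear on chance, too few for a share under 0.05. In 3 of them as many probes stood apart as the 146 of the genotypes, the real one included, and the highest other held 196, with both genotypes at 0 h and WT at 24 h against the rest. Probes of the deleted gene could be among the 48 running-number probes seen on all WT and no ΔcyaI arrays. Of these 48, 3 were at least 4-fold lower in ΔcyaI at 3 h. With no pairing of probes and genes, probes of the deleted gene cannot be told apart from other differences.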

How the results depend on the processing

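Of the alternatives in this part, normexp on the median signal, the common floor and counts among probes measured in both groups, or in all 4, were chosen after seeing the data. Of the values without 1 array, 38 of 44 counts of calls, 187 of 220 probe group medians, 11 of 16 correlations and all 240 values of running-number probes stayed, meaning within 1.5 times for a count and in the same direction on the same side of the threshold for a change. Under the other alternatives 88 of 117 counts and 444 of 445 values of running-number probes did. Of 585 probe group medians under the other alternatives, 487 kept direction and call and 31 gained a call (25 of them of LEADER2), as did 12 without 1 array (8 of LEADER2). Signal over background limits the dim probes, since the lowest well-above-background level lay between -2.60 and -1.02. Where no construction is named, the cause was not tested.

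With an added minimum of 1 on the absolute log2 scale, which can only remove calls, calls numbered 8367 for WT 3 h vs 0 h, 6915 for WT 24 h vs 0 h, 14631 for ΔcyaI 3 h vs 0 h, 16030 for ΔcyaI 24 h vs 0 h, 10060 for ΔcyaI vs WT at 0 h, 3012 for ΔcyaI vs WT at 3 h, 6497 for ΔcyaI vs WT at 24 h and 9378 for the difference of the 3 h changes. Counting only probes measured in both groups, which leaves fewer probes, calls numbered 16530 for ΔcyaI 24 h vs 0 h and 8580 for ΔcyaI vs WT at 24 h. Counting only probes measured in all 4 groups, which leaves fewer probes, calls numbered 10223 for the difference of the 24 h changes. With normexp on the median signal and quantile normalization, the median turned sign, to 0.016 for CRISPR1 in WT 3 h vs 0 h and 0.13 for LEADER1 in WT 3 h vs 0 h. The call was lost at a median of 0.37 for LEADER1 in ΔcyaI vs WT at 24 h. There the correlation was 0.708 for WT and ΔcyaI changes at 3 h and 0.658 for WT and ΔcyaI changes at 24 h. With quantile normalization, the median turned sign, to 0.0071 for CRISPR1 in WT 3 h vs 0 h, 0.12 for LEADER1 in WT 3 h vs 0 h and -0.044 for CRISPR2 in the difference of the 24 h changes. Calls were lost at medians of -0.15 for CRISPR2 in WT 3 h vs 0 h, -0.62 for LEADER1 in WT 24 h vs 0 h and 0.41 for LEADER1 in ΔcyaI vs WT at 24 h. With arrays centred on their medians, the median turned sign, to -0.056 for CRISPR2 in WT 24 h vs 0 h. The call was lost at a median of 0.84 for LEADER1 in ΔcyaI vs WT at 24 h. With the authors' processed values, calls numbered 13361 for ΔcyaI 3 h vs 0 h, 14592 for ΔcyaI 24 h vs 0 h, 2567 for ΔcyaI vs WT at 3 h, 5059 for ΔcyaI vs WT at 24 h and 10959 for the difference of the 24 h changes. There the median turned sign, to 0.34 for CRISPR1 in WT 3 h vs 0 h, 0.34 for CRISPR2 in WT 3 h vs 0 h, 0.37 for LEADER1 in WT 3 h vs 0 h, 0.15 for CRISPR1 in WT 24 h vs 0 h, -0.053 for CRISPR2 in ΔcyaI 24 h vs 0 h, -0.14 for CRISPR1 in the difference of the 3 h changes, -0.30 for CRISPR2 in the difference of the 3 h changes, -0.16 for CRISPR3 in the difference of the 3 h changes, -0.23 for CRISPR2 in the difference of the 24 h changes, -0.099 for CRISPR3 in the difference of the 24 h changes and -0.28 for LEADER1 in the difference of the 24 h changes. There the median of all probes moved to 0.40 and 0.21 in WT at 3 and 24 h, -0.10 in ΔcyaI at 24 h and -0.45 and -0.32 in the 3 h and 24 h differences, and relative to it only CRISPR2 in the 24 h difference changed side, of the 11 that turned. Calls were lost at medians of 0.29 for CRISPR3 in WT 24 h vs 0 h, 0.81 for CRISPR1 in ΔcyaI vs WT at 0 h and 0.35 for CRISPR2 in ΔcyaI vs WT at 24 h. There the correlation was 0.66 for WT and ΔcyaI changes at 24 h. With no filter, which tests more probes, calls numbered 43886 for ΔcyaI 24 h vs 0 h, 37440 for ΔcyaI vs WT at 0 h, 29373 for ΔcyaI vs WT at 24 h and 32594 for the difference of the 24 h changes. There the median turned sign, to -0.031 for CRISPR2 in WT 24 h vs 0 h. Calls were lost at medians of -0.29 for CRISPR2 in WT 3 h vs 0 h, 0.74 for CRISPR3 in ΔcyaI 24 h vs 0 h, 0.53 for LEADER1 in ΔcyaI vs WT at 24 h and 0.98 for CRISPR1 in the difference of the 24 h changes. There the correlation was 0.624 for WT and ΔcyaI changes at 3 h and 0.514 for WT and ΔcyaI changes at 24 h. With only probes above background on all 12 arrays, which tests fewer, calls numbered 9596 for WT 3 h vs 0 h, 8778 for WT 24 h vs 0 h, 13957 for ΔcyaI 3 h vs 0 h, 14715 for ΔcyaI 24 h vs 0 h, 12167 for ΔcyaI vs WT at 0 h, 8241 for ΔcyaI vs WT at 24 h, 9358 for the difference of the 3 h changes and 10506 for the difference of the 24 h changes. There the median turned sign, to 0.17 for CRISPR1 in WT 3 h vs 0 h, 0.75 for CRISPR1 in WT 24 h vs 0 h, -0.13 for CRISPR2 in WT 24 h vs 0 h, -0.68 for CRISPR2 in ΔcyaI 3 h vs 0 h, -0.70 for CRISPR2 in ΔcyaI 24 h vs 0 h, -0.81 for CRISPR1 in ΔcyaI vs WT at 0 h, -0.47 for CRISPR1 in ΔcyaI vs WT at 3 h, -0.73 for CRISPR1 in ΔcyaI vs WT at 24 h and -0.012 for CRISPR2 in the difference of the 24 h changes. This filter removes CRISPR1 probes dim in WT and leaves mainly probes 1 to 14, so CRISPR1 as a group was then called lower in ΔcyaI at all 3 times. The remaining probes of 15 to 41 were not lower. CRISPR1 in WT 24 h vs 0 h and CRISPR2 in ΔcyaI 24 h vs 0 h were called too. Calls were lost at medians of 0.18 for CRISPR2 in ΔcyaI vs WT at 24 h, 0.53 for LEADER1 in ΔcyaI vs WT at 24 h, 0.46 for CRISPR1 in the difference of the 3 h changes and 0.26 for CRISPR1 in the difference of the 24 h changes. There the correlation was 0.641 for WT and ΔcyaI changes at 3 h. With a common floor, calls numbered 9448 for ΔcyaI vs WT at 24 h. Calls were lost at medians of 0.00 for CRISPR3 in WT 24 h vs 0 h, 0.00 for CRISPR1 in ΔcyaI vs WT at 0 h and 0.092 for CRISPR2 in ΔcyaI vs WT at 24 h. There the correlation was 0.671 for WT and ΔcyaI changes at 3 h and 0.632 for WT and ΔcyaI changes at 24 h. With fry, the call was lost at a median of 0.23 for CRISPR3 in WT 24 h vs 0 h. With an estimated correlation in camera none of the 20 probe group calls passed, among them those with medians of 1.69 for CRISPR1 in ΔcyaI vs WT at 0 h, 0.75 for CRISPR2 in ΔcyaI vs WT at 0 h, 3.19 for CRISPR3 in ΔcyaI vs WT at 0 h, 2.68 for CRISPR1 in ΔcyaI vs WT at 3 h, 0.91 for CRISPR2 in ΔcyaI vs WT at 3 h, 3.77 for CRISPR3 in ΔcyaI vs WT at 3 h, 2.88 for CRISPR1 in ΔcyaI vs WT at 24 h, 0.56 for CRISPR2 in ΔcyaI vs WT at 24 h and 3.59 for CRISPR3 in ΔcyaI vs WT at 24 h.

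Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, the counts ranged from 2679 to 4945 for ΔcyaI vs WT at 3 h, 9266 to 13812 for the difference of the 3 h changes and 8913 to 12185 for ΔcyaI vs WT at 24 h. The count at 3 h was 2679 without ΔcyaI 3 h replicate 1, 2835 without ΔcyaI 3 h replicate 2 and 3481 without WT 3 h replicate 1. That at 24 h was 8913 without WT 24 h replicate 2 and 9200 without ΔcyaI 24 h replicate 2, and that of the 3 h changes was 9266 without ΔcyaI 3 h replicate 1. The correlation ranged from 0.573 to 0.619 for WT and ΔcyaI changes at 24 h and 0.659 to 0.693 for WT and ΔcyaI changes at 3 h. Medians whose sign turned without 1 array ranged from -0.18 to 0.26 for CRISPR2 in the difference of the 24 h changes, -0.075 to 0.20 for LEADER1 in ΔcyaI vs WT at 0 h, -0.20 to 0.12 for LEADER1 in the difference of the 3 h changes, -0.11 to 0.17 for CRISPR2 in WT 24 h vs 0 h, -0.10 to 0.12 for CRISPR1 in WT 24 h vs 0 h, -0.16 to 0.29 for CRISPR3 in WT 3 h vs 0 h and -0.20 to 0.011 for LEADER1 in ΔcyaI vs WT at 3 h.

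The replicate numbers did not pair the arrays, as deviations of same-numbered arrays within a genotype correlated at -0.366 to 0.231. With the number as a replicate block within genotype, calls numbered 5207 to 25464 over the comparisons, and across genotypes 6578 to 26153, all within 1.5 times. Not run were normexp on the mean signal, and all alternatives for cyaI and the gene lists, which matched no probe. The median of probes per feature equals the mean with 1 probe each, and the fit to 1 slide equals that to the arrays compared.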

Other observations

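The probe sets in this part were chosen after the values were seen. Of the 96 probes well above background on all ΔcyaI and no WT arrays, 34 were CRISPR or leader probes, a kind that made up 114 of the 37703 probes tested. The other 62 carried running numbers, and 39 of these were at least 4-fold higher in ΔcyaI at 3 h. Of the 50 seen on all WT and no ΔcyaI arrays, 2 were CRISPR probes, R_CRISPR1-48 and R_CRISPR1-49, and 48 carried running numbers.

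The genotype differences at the 3 times share no arrays. Across probes, which are not independent replicates, those at 3 h and 24 h correlated at 0.557, those at 0 h and 3 h at 0.306, and those at 0 h and 24 h at 0.266. Of 4075 probes called at both 3 h and 24 h, 90.6% differed the same way, with 1762 higher and 1931 lower in ΔcyaI at both times, against 553 and 752 for independent lists. The share was 72.9% of 4228 for 0 h and 3 h, and 69.1% of 8337 for 0 h and 24 h. The order of these correlations was not tested.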
